A study of Mus musculus with 2 samples.

How the data were processed

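Single-cell RNA sequencing was done on immune cells sorted from mouse gliomas, as living CD45.2-positive CD45.1-negative cells, which the labels call endogenous. Libraries were made with the BD Rhapsody system, which captures single cells with barcoded beads in microwells. There were 2 libraries, 1 from tumours given PBS (phosphate-buffered saline) and 1 from tumours given EM, sampled at 72 h per its title. The labels do not say what EM stands for, nor how many animals went into a library.

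The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, per the file headers and the values, which are whole numbers. Per the submitters' processing notes, CASAVA 1.8 and STARsolo were used with the mm10 genome. The annotation and the cell calling are not given in the sources used here, and no barcode in either library held fewer than 500 UMIs. All CPM, log2 ratios and shares were computed here from these deposited counts. Gene positions were taken by gene identifier from the GENCODE annotation of GRCm38, the same assembly as mm10, in which 31184 of the 31253 genes were found.

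The PBS matrix held 8333 barcodes and 45043934 UMIs (median 4109 per barcode), and the EM matrix 8039 barcodes and 19385631 UMIs (median 2006). Cells with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. The mitochondrial limit was passed by 573 PBS barcodes (6.88%) and 64 EM barcodes (0.796%). Scrublet, run per library through scanpy 1.11.5, called 11 PBS cells (0.142%) and 10 EM cells (0.126%) as doublets. These shares are too low for the caller to have worked, so doublets remain in the data, and an alternative that also removed the 6% of cells with the highest doublet scores was added after seeing the data. The cells kept were 7745 PBS cells (median 4299 UMIs and 1931 genes) and 7957 EM cells (median 2016 UMIs and 1103 genes).

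Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components without integration, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 gave 33 clusters. Clusters were named from marker lists fixed before the data were examined. The scoring rule was set after seeing the data: a marker score of at least 0.3, at least 3 detected markers, and leading genes that did not favour another class when compared with cells outside the class. It left 4 clusters unnamed. A first version of the rule for clusters of few UMIs put cluster 19 (227 PBS and 11 EM cells) among T cells, and a correction of that rule left it unnamed. When leading genes were taken against all other cells instead, clusters 0 and 11 (T) and cluster 10 (monocyte/macrophage) held more markers of another class than of their own, so values without them, and values for clusters by number, are also given, both chosen after seeing the data. A regulatory T-like subset was added after seeing the data. A CD8-like subset was tried and left out, because its size depended on a score limit set after seeing the data.

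UMIs were summed per library and class and expressed as CPM, and the log2 ratio of EM over PBS was taken without a pseudocount. With 1 library per group there was no test, and no spread between animals could be estimated. Shares carry exact Clopper-Pearson 95% intervals, and ratios of counts carry exact 95% intervals from the conditional binomial distribution. All intervals cover counting error only. A count of 0 was given a limit of 3 counts. Gene lists were fixed before the data were examined. A list's median log2 ratio was taken over members with at least 20 UMIs in the class and set as a percentile among 10000 random lists of the same size matched on expression, which describes these 2 libraries and is no p-value. Classes with at least 100 cells in each library were compared.

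The named genes follow a rule fixed before the data were examined. Among genes with at least 50 CPM in the higher library, at least 100 UMIs and an interval excluding equality, the rule took the 10 highest and 10 lowest ratios in the monocyte/macrophage class and the 5 highest and 5 lowest in each other class. It left out mitochondrial, ribosomal, haemoglobin and receptor-segment genes, unnamed gene models and markers of other classes. It added, per list, the 2 highest and 2 lowest members above 10 CPM, and a set of genes given whatever their values. Genes taken from single clusters or used in the closing tests were chosen after seeing the data. The text prints part of the genes that the rule took, and a gene that it named in microglia is not reported here.

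The ratio and list steps were tested on simulated counts with 200 changed genes, drawn as Poisson counts from the summed profile of both libraries. Such counts hold no extra spread between cells and no difference in cluster mix, so they check the calculation only. In the monocyte/macrophage class (9125 genes), doubled genes came out at a median log2 ratio of 0.99, the 95% interval held the true ratio for 96% of genes, and 8 of 100 unchanged lists lay outside the central 95% of random lists. In T cells (10258 genes) the same values were 0.99, 95.6% and 6 of 100. Alternatives were a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), no doublet removal, Leiden resolutions of 0.5 and 2.0, centring within each library, median-of-ratios size factors, a pseudocount of 10 CPM, equal weight per cell, no UMI minimum and thinning to 1000 UMIs. Thinning left out cells with under 1000 UMIs, so it changed the mix of cells as well as the depth. Removal of the highest doublet scores, cluster 16 counted with neutrophils, the clusters left out, cluster 9 alone and subtraction of T cell RNA were chosen after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.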

Results

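Endogenous immune cells were sorted from mouse gliomas given EM or PBS, and 1 library of each was sequenced. The labels give 72 h for the EM library and no time for the PBS library. The series title concerns adoptive macrophages and a reversal of the immunosuppressive tumour environment, so the comparison asks how the host immune cells of the tumour differed between EM and PBS. After filtering, the PBS library held 7745 cells and 43468766 UMIs, and the EM library 7957 cells and 19264694 UMIs. No difference below has a replicate check. The libraries also differed in sex-linked transcripts: Xist, the RNA that silences 1 X chromosome in female cells, stood at 10.6 CPM in PBS and 384 CPM in EM, and the Y-linked gene Ddx3y at 192 and 4.41 CPM. Any difference between EM and PBS is therefore also a difference between libraries of unlike sex-linked expression.

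Neutrophils, the short-lived granulocytes of acute inflammation, made up 8.32% of PBS cells (644 cells, 95% interval 7.71 to 8.95%) and none of the 7957 EM cells (0 to 0.0463%). The PBS share was 220.5-fold the limit of 3 counts (0.0377%), without its own counting error. The exact 95% interval of the ratio of EM over PBS reached up to 0.00559. Cluster 16, left unnamed because its highest marker score, for neutrophils, was 0.205 and below the limit of 0.3, held 256 PBS cells and 27 EM cells. Counted with neutrophils it would make the shares 11.6% and 0.339%, but it had S100a9, a main neutrophil transcript, at 63.7 CPM in PBS, against 15950 CPM in the neutrophils. Retnlg, a leading gene of neutrophil cluster 15, stood at 10510 CPM in PBS cells and 5115 CPM in EM cells of cluster 16, against 4077 CPM in the neutrophils. Ccr3, a chemokine receptor known from eosinophils and a leading gene of cluster 16, stood at 299 CPM in its PBS cells and 1186 CPM in its EM cells, against 0.851 CPM in the neutrophils. Monocyte/macrophage cells were 20.8% of PBS cells and 8.66% of EM cells, a ratio of 0.416 (0.380 to 0.455). Natural killer (NK) cells were 4.14% and 8.37%, a ratio of 2.02 (1.77 to 2.31), and dendritic cells, which present antigen to T cells, were 1.83% and 4.94%, a ratio of 2.69 (2.22 to 3.29). Regulatory T-like cells, named from Foxp3 and related markers, were 2.30% of PBS cells and 12.9% of EM cells, a ratio of 5.61 (4.78 to 6.62), and 4.34% and 19.4% of the T class.

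T cells as a whole were 53.0% of PBS cells and 66.3% of EM cells, a ratio of 1.25 (1.20 to 1.30), but without clusters 0 and 11 the ratio turned to 0.750. Those clusters held 8 and 6 T markers and 0 of another class among their leading genes against cells outside the T class. Microglia, the resident macrophages of the brain, were 2.60% and 4.85%, a ratio of 1.87 (1.57 to 2.23) that turned to 0.620 under the stricter cell filter. That filter also moved the monocyte/macrophage ratio to 0.232 and the dendritic ratio to 4.73. Plasmacytoid dendritic cells, known as producers of type I interferon, numbered 2 in PBS and 182 in EM. Basophil/mast cells numbered 4 and 179, B cells 55 and 120, and plasma cells 52 and 22. Unnamed clusters held 607 PBS cells (7.84%) and 43 EM cells (0.540%). The shares are of sorted cells that passed a UMI minimum at unequal depth, and all names come from rebuilt clusters.

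**Figure D1:**
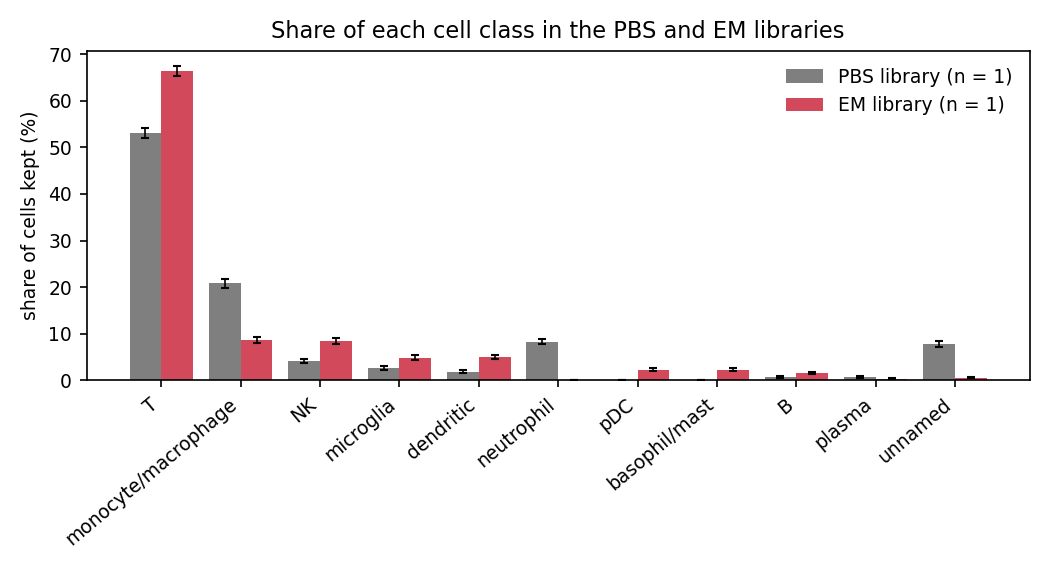
Share of cells kept, in percent, for each cell class in the PBS library (grey) and the EM library (red), 1 library each, with exact 95% intervals for counting error only as error bars. T cells were the most frequent class in both, and neutrophils were 8.32% of PBS cells and 0 of EM cells.

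In monocyte/macrophage cells the type I interferon list, genes known to be induced by interferon alpha and beta, was higher in EM in all 25 measured members, with a median log2 ratio of 2.73 at the 100th percentile of random lists. Alternative activation genes, associated with tissue repair, were lower, with 12 of 18 members lower and a median of -1.00 at percentile 0. Hypoxia genes were lower in all 15 measured members, with a median of -1.41 at percentile 0. The immunosuppressive and angiogenic list was lower in 12 of 19 members, with a median of -0.62 (-0.74 with the undetected member at its limit) at percentile 0.27. This median lay within the central range of random lists under the stricter cell filter (-0.086, percentile 38.1), at resolution 2.0 (-0.15, percentile 26.8) and in cluster 9 alone (-0.34, percentile 3.31). Classical activation genes, associated with inflammatory macrophages, went both ways, with 8 of 17 higher and a median of -0.05 at percentile 38.5. That median was below random lists with equal weight per cell (-1.12, percentile 0), at 1000 UMIs per cell (-0.41, percentile 1.48), with T cell RNA subtracted (-0.44, percentile 2.07) and in cluster 9, and it was above 0 within their range under the stricter cell filter (0.059), at resolutions 0.5 (0.012) and 2.0 (0.15) and with centring (0.071). T cell markers stood in these cells at 9.43% of their T cell level in EM, against 2.54% in PBS.

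Arg1, the enzyme that breaks down arginine (chromosome 10, 24915221 to 24927484, mm10), stood at 1084 CPM in PBS and 114 CPM in EM, a log2 ratio of -3.25 (95% interval -3.48 to -3.03). The mannose receptor Mrc1 (chromosome 2, 14229392 to 14332057), which is also a marker used for naming, stood at 1151 and 107 CPM (-3.43, -3.67 to -3.20). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), stood at 83.3 and 1.39 CPM (-5.91, -8.96 to -4.05), from 2 UMIs in EM. The chemokine Ccl24 had a log2 ratio of -3.86, the hypoxia-responsive growth factor Vegfa -3.03 and the lipid droplet gene Hilpda -3.88. Il1b, which codes for interleukin 1 beta, was lower (-1.95), as were the checkpoint ligand Cd274 (-1.45), the chemokine Cxcl9 (-1.58) and the costimulatory gene Cd86 (-0.64). Tnf was higher (1.16, 1.03 to 1.29), as was the costimulatory receptor gene Cd40 (2.01). For Il10 the interval included equality (0.46, -0.15 to 1.03). Tgfb1 stood at 86.3 and 105 CPM (0.28, 0.03 to 0.52), and its sign turned with equal weight per cell.

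The interferon-induced gene Isg20 (chromosome 7, 78913424 to 78920396) stood at 8.68 and 420 CPM, a log2 ratio of 5.59, and Rsad2, which ranked below the 10 highest genes, at 46.9 and 898 CPM (4.26). Ifit3b (5.20), Slfn4 (4.69), S100a4 (4.57), Cd7 (5.47), Bcl11a (6.47), Kdr (7.20), Pdlim1 (4.88) and Apod (6.50) were, with Isg20, the genes among the 10 highest other than Xist. Under the stricter cell filter the sign of Apod turned and the class ratios of Kdr and Bcl11a were 4.80 and 3.24. Both were then among the leading genes of a cluster classed as dendritic, with 132 EM cells, 111 of them from cluster 14. Pla2g2d (-7.45), Palld (-6.75), Clec1b (-6.30), the iron exporter gene Slc40a1 (-6.19), complement C6 (-5.43) and Gbp2b (-5.33) were among the lowest, together with X-linked Tspan7 (-6.33) and Mucl1, at least 76.0-fold lower with 0 UMIs in EM.

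Interferon gamma response genes were higher in 12 of 20 members (median 0.60, percentile 99.9), with Cxcl10 at a log2 ratio of 1.81 and Gbp6 at -1.99. That median was -0.056 with equal weight per cell and 0.32 (percentile 95.9) at 1000 UMIs per cell. MHC class I genes were higher in 15 of 17 members (0.39, percentile 95.9) and MHC class II genes lower in 9 of 11 (-0.31, percentile 7.97). The MHC class II median was 0.15 (percentile 63.2) with equal weight per cell and -0.77 (percentile 0.34) under the stricter cell filter. The MHC class I median was above random lists at resolution 2.0 (0.56), without cluster 10 (0.56) and in cluster 9 (0.54). It was also above them at 1000 UMIs per cell (0.45) and under the stricter cell filter (0.43). Glycolysis (-0.68, percentile 0.13), lysosome and phagocytosis (-0.62, percentile 0.055) and lipid-associated genes (-0.65, percentile 0.21) had lower medians, with Mertk, a receptor for engulfing dead cells, at -3.86 and the cholesterol exporter gene Abca1 at -3.05. With equal weight per cell the lysosome (0.14) and lipid-associated (0.15) medians turned and glycolysis (-0.48, percentile 2.67) lay within the central range. At resolution 2.0 lipid-associated (-0.39) and glycolysis genes (-0.30) lay within it, as did lipid-associated genes at 1000 UMIs per cell (-0.24). Chemokines (-0.34, percentile 3.25), NF-kB targets (-0.20, percentile 10.6) and oxidative phosphorylation (-0.11, percentile 27.5) had medians below 0 within the central range of random lists, and above 0 in cluster 9 (chemokines, 0.37), under the stricter cell filter (NF-kB targets, 0.075) and with equal weight per cell (oxidative phosphorylation, 0.11). With equal weight per cell, NF-kB targets (-0.81) and dissociation stress genes (-0.36) were below random lists. NF-kB targets were also below them at 1000 UMIs per cell (-0.45, percentile 0.92). Chemokines were below them without the highest doublet scores (-0.41, percentile 1.79) and with T cell RNA subtracted (-0.44, percentile 1.4). Dissociation stress (0.13, percentile 69.6) and the unfolded protein response (0.31, percentile 92.5) lay within the range in the summed counts. Proliferation lay above it (0.40, percentile 99.6) but within it without cluster 10 (0.11) and in cluster 9 (0.10). Cluster 30 of this class, with the cell cycle genes Cdk1, Ccnb1 and Birc5 among its leading genes, held 60 PBS cells and 0 EM cells. The list of non-immune cell genes had 4 measured members and a median of -0.95 (percentile 11.7).

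Different clusters held most of this class in each library. Clusters 6 and 10 held 890 and 447 PBS cells and 1 and 5 EM cells, while clusters 9 and 14 held 175 and 39 PBS cells and 416 and 267 EM cells. Cluster 14 had Rsad2, Cxcl10 and Slfn4 among its leading genes. Cluster 9, with complement C1q genes and the microglial marker Olfml3 among its leading genes, was the 1 cluster with at least 100 cells of each library. Its PBS cells were 10.9% of the PBS class and had a median of 1589 UMIs, against 9176 for that class. They may therefore not stand for the PBS class. In cluster 9 the type I interferon median was 2.18, the alternative activation median -1.45 and the hypoxia median -1.00, and Arg1 and Mrc1 were lower (-1.65, -1.93 to -1.38, and -1.41, -1.75 to -1.08). NF-kB targets (-1.17), dissociation stress genes (-1.38), classical activation genes (-1.10) and Tnf (-1.60) were lower in cluster 9, where the intervals of Cd86 (0.39, -0.16 to 0.95) and Nos2 (-2.08, -5.33 to 0.20) included equality, lipid-associated (0.52) and lysosome genes (0.46) were higher, and MHC class II genes had a median of 0.53. The nuclear RNA Malat1 stood in cluster 9 at 1077 CPM in PBS and 508 CPM in EM. The T cell gene Cd3e stood there at 138 CPM in PBS and 169 CPM in EM, against 838 and 1101 CPM in T cells. With cluster 10 left out of the class, the type I interferon median was 2.84 and the alternative activation median -1.00.

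**Figure D2:**
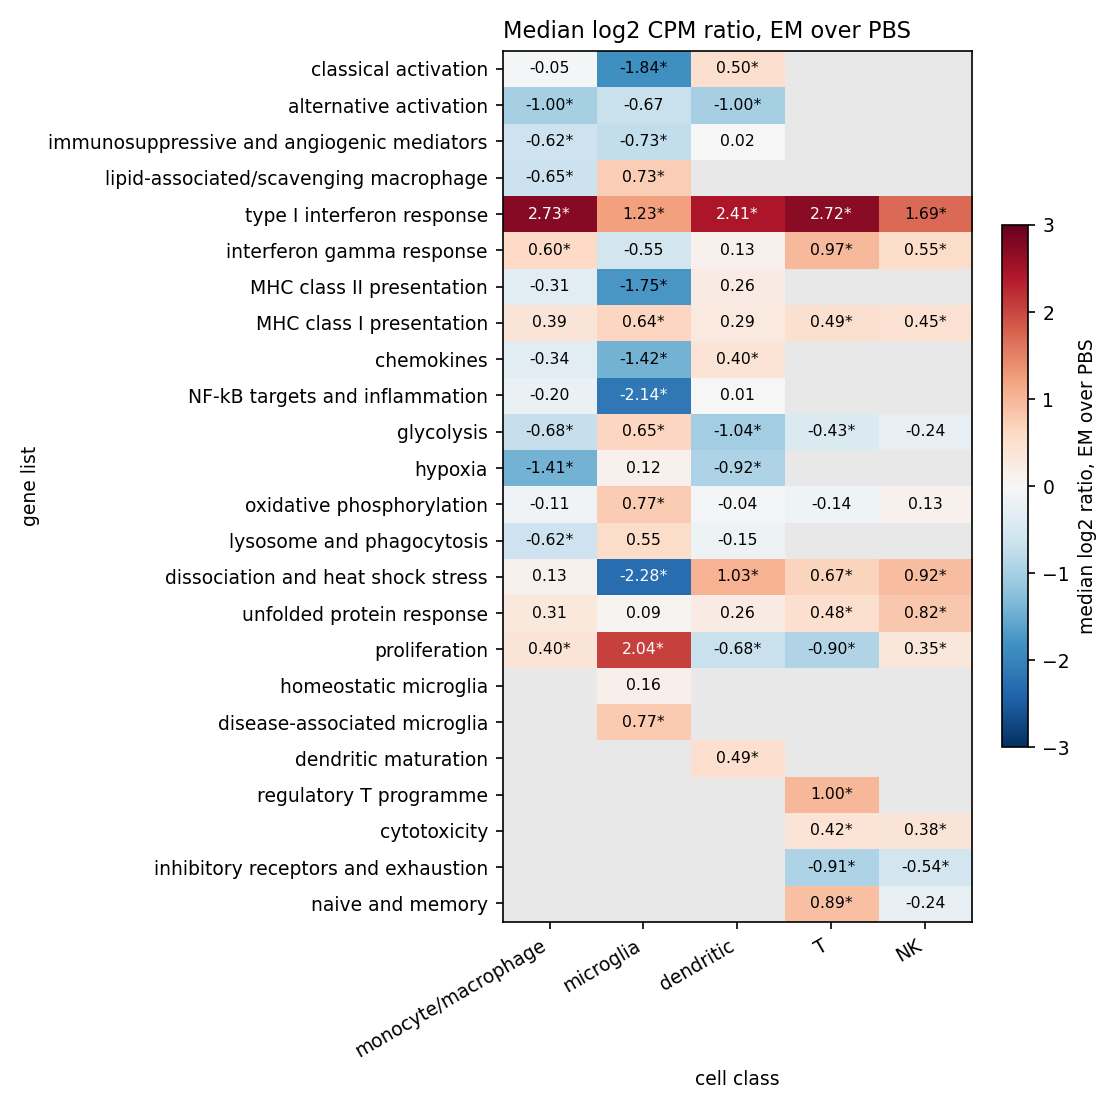
Median log2 CPM ratio of EM over PBS for each gene list (rows) in each cell class (columns), 1 library per group. An asterisk marks a median outside the central 95% of 10000 random lists of matched expression, and a grey field is a list not described in that class. The type I interferon list was higher in each of the 5 classes, from 1.23 in microglia to 2.73 in monocyte/macrophage cells.

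**Figure D3:**
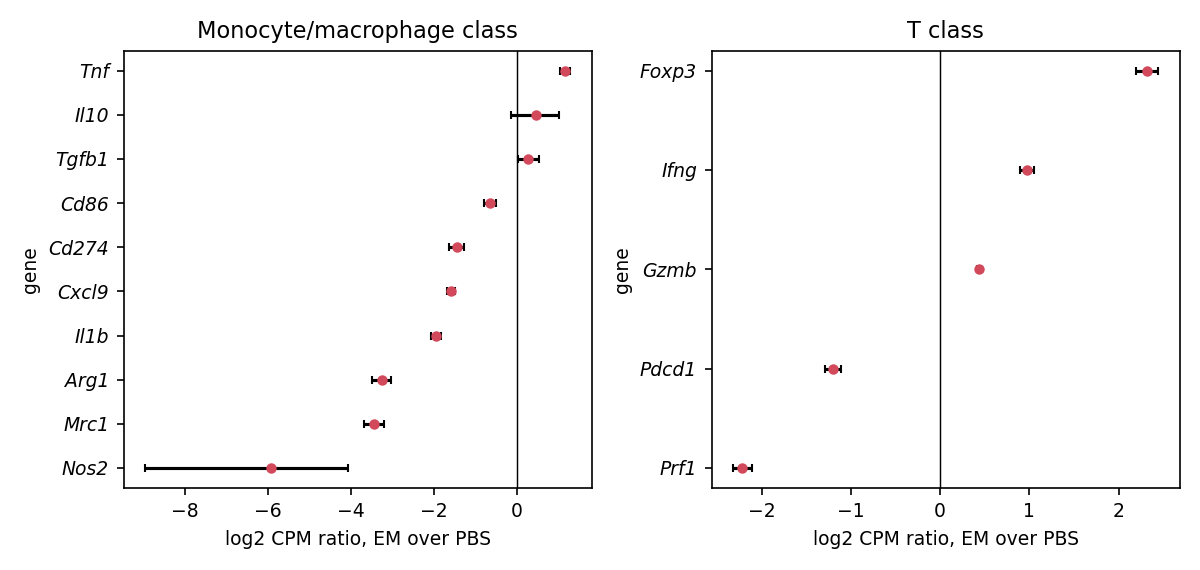
Log2 CPM ratio of EM over PBS for genes fixed before the data were examined, in the monocyte/macrophage class (left) and the T class (right). Points are ratios of summed counts from 1 library per group and bars are exact 95% intervals for counting error. Arg1, Mrc1 and Nos2 lay below -3 and Tnf above 1.

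Microglia in EM had lower medians of NF-kB target, classical activation and dissociation stress genes, and higher medians of disease-associated and proliferation genes, than in PBS. NF-kB targets were lower in 17 of 18 measured members (median -2.14), classical activation genes in 12 of 14 (-1.84) and MHC class II genes in all 11 (-1.75), each at percentile 0. The transcription factor genes Egr2 (-6.80, -8.43 to -5.58) and Egr3 (-8.08, 1 UMI in EM), the chemokine Ccl2 (-3.30) and Il1b (-3.91) were lower, as were Cass4 (-6.37) and Zfp608 (-6.23), each with 1 UMI in EM. The highest were Fcrls (7.03), a marker used for naming, and the chemokine Cxcl13 (4.68), both among the leading genes of cluster 12. Disease-associated genes were higher in 13 of 16 members (0.77, percentile 99.6), with lipoprotein lipase Lpl at 2.78 and Fabp5 at 2.29 but Apoe at -0.98. The type I interferon list was higher in 21 of 25 members (1.23, percentile 100), with Isg20 at 2.54 and Ifih1 at -1.45.

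The dissociation stress list, genes known to be induced by handling of tissue, was lower in 17 of 20 microglial members (-2.28, percentile 0), with Egr1 at -4.27 but the chaperone genes Hspe1 (1.11) and Hsp90ab1 (0.88) higher. Proliferation genes were higher in 15 of 17 (2.04, percentile 100), with Stmn1 at 3.13. Oxidative phosphorylation (0.77), glycolysis (0.65), lipid-associated (0.73) and MHC class I genes (0.64) had medians above the central range of random lists, and chemokines (-1.42) and immunosuppressive mediators (-0.73) below it, the last within it with equal weight per cell (-0.59) and with T cell RNA subtracted (-0.62). Interferon gamma response (-0.55), alternative activation (-0.67), lysosome (0.55), hypoxia (0.12, or -0.050 with the undetected member at its limit), unfolded protein response (0.086) and homeostatic genes (0.16), several of which also named the class, lay within it. But the lysosome median lay above it with equal weight per cell (0.83) and with T cell RNA subtracted (0.72). The interferon gamma median lay below it with T cell RNA subtracted (-0.77), and the alternative activation median without the UMI minimum (-0.89). The T cell genes Thy1 (3.06) and Gzmb (3.72) were higher in EM microglia, where T cell markers stood at 13.4% of their T cell level, against 2.42% in PBS. Microglia were mostly cluster 20 in PBS (186 cells) and cluster 12 in EM (379 cells), with medians of 8096 and 900.5 UMIs for the class. The nuclear RNA Malat1 stood at 2282 CPM in the PBS cells of cluster 20 and 635 CPM in the EM cells of cluster 12. Median-of-ratios scaling gave a size factor of 0.19 on the log2 scale, by which each microglial ratio would be lower.

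Dendritic cells had higher type I interferon genes in EM, in all 25 members (median 2.41, percentile 100), with the transcription factor Irf7 at 23.8 and 310 CPM (3.70, 3.15 to 4.31). Dendritic maturation genes were higher in 9 of 12 members (0.49, percentile 99.8), with Cd40 at 1.48 and the interleukin 12 subunit Il12b at 1.76, while the costimulatory genes Cd80 (-1.78) and Cd86 (-0.94) were lower. Alternative activation was lower in 12 of 15 members (-1.00, or -1.25 with undetected members at their limits), and glycolysis in 13 of 14 (-1.04), each at percentile 0. Ch25h, an enzyme that makes 25-hydroxycholesterol, was at least 53.5-fold lower with 0 UMIs in EM, and Mmp12 (-4.02) and Trem1 (-3.75) were also lower. Hypoxia (-0.92) and proliferation (-0.68) had lower medians and dissociation stress (1.03), classical activation (0.50) and chemokines (0.40) higher ones, all outside the central range of random lists. With equal weight per cell and without the UMI minimum, the classical activation medians (0.28 and 0.24) lay within that range and the chemokine medians turned to -0.0097 and -0.083. MHC class I (0.29), MHC class II (0.26), interferon gamma (0.13), unfolded protein response (0.26), NF-kB (0.012), immunosuppressive (0.020), oxidative phosphorylation (-0.043) and lysosome genes (-0.15) lay within it. With equal weight per cell the MHC class I median lay above it (0.35, percentile 97.8). T cell markers stood in dendritic cells at 10.7% of their T cell level in EM, against 3.72% in PBS. Cluster 25, scored highest for the cDC2 subset, held 70 of the 142 PBS cells, and cluster 18, scored highest for the cDC1 subset, held 216 of the 393 EM cells. Cluster 23, migratory dendritic cells, was 16.9% of the class in PBS and 31.8% in EM. The maturation list shares Ccr7, Fscn1 and Ccl22 with the migratory markers. The alternative activation list shares Mgl2 and Clec10a with the cDC2 markers and Ccl17 and Ccl22 with the migratory ones. The mix of subsets may move both medians, which were not taken within clusters.

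T cells had higher type I interferon genes and lower inhibitory receptor genes in EM. Against all other cells, many of them T cells, clusters 0 and 11 held 1 and 2 markers of another class and 0 of their own among their leading genes. Against cells outside the T class they held 8 and 6 T markers and 0 of another class. Clusters are therefore compared by number first. The type I interferon median was 0.99 in cluster 0, 1.70 in cluster 1, 1.83 in cluster 3, 1.96 in cluster 4, 2.45 in cluster 7 and 1.30 in cluster 8, each at percentile 100. The inhibitory receptor median was -0.67 in cluster 0, -1.00 in cluster 1, -0.82 in cluster 7 and -0.60 in cluster 8, but 0.0053 in cluster 3, the regulatory T-like cells, and -0.036 in cluster 4. The cytotoxicity median was above 0 in each of these 6 clusters, from 0.19 in cluster 1 to 1.13 in cluster 3, but in clusters 1 (percentile 82.1) and 8 (0.22, percentile 97.0) it lay within the central range of random lists.

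**Figure D4:**
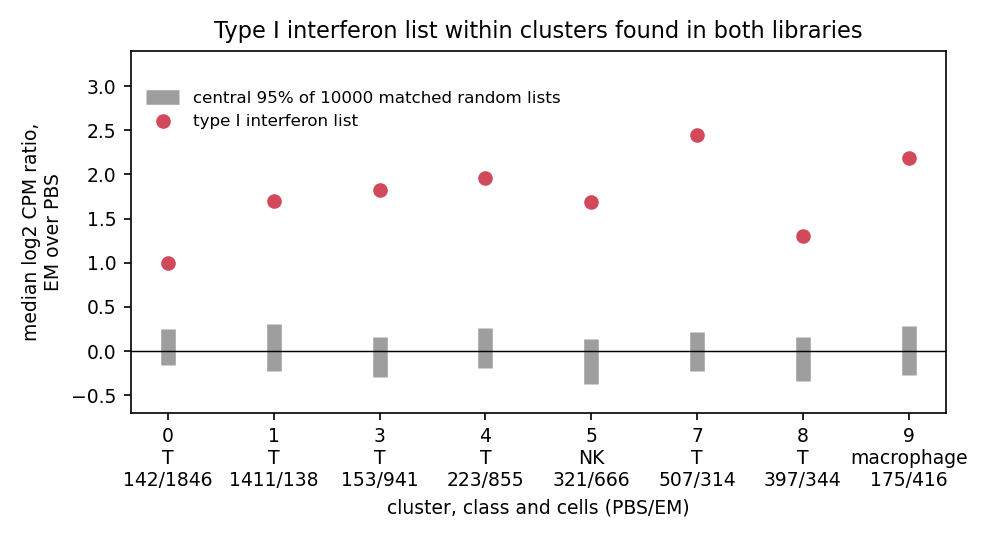
Median log2 CPM ratio of EM over PBS of the type I interferon list (points) within each cluster that held at least 100 cells of each library, with the central 95% of 10000 matched random lists (grey bars). The medians lay between 0.99 and 2.45, above the random lists in all 8 clusters.

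Over the whole T class the type I interferon list was higher in all 25 members (median 2.72), with Oasl2 at 4.03 and Ifi44 at 5.78, and the inhibitory list lower in 12 of 14 (-0.91). Pdcd1, the gene of the checkpoint receptor PD-1 (225 and 98.2 CPM, -1.20, -1.29 to -1.11), and Havcr2 (-1.43) were lower, although Pdcd1 was higher in cluster 3 (1.00, 0.39 to 1.66), and in cluster 4 the interval included equality (0.67, -0.13 to 1.54). Interferon gamma, Ifng, was higher (118 and 231 CPM, 0.97, 0.89 to 1.05), as was granzyme B, Gzmb (0.43, 0.41 to 0.45), and perforin, Prf1, was lower (309 and 66.5 CPM, -2.22, -2.32 to -2.11). By cluster, Gzmb was lower in cluster 8 (-1.20, -1.62 to -0.80) and its interval included equality in cluster 1 (-0.07, -0.19 to 0.05), and the interval of Prf1 included equality in clusters 0, 3 and 4. The chemokine Xcl1 (3.46) and the quiescence-associated factor Klf2 (2.67, with an interval that included equality in cluster 8) were higher, and Gzmd (-5.73) and Serpinb9b (-5.44) lower. The cytotoxicity median was 0.42 over the class and -0.58 without clusters 0 and 11. Foxp3 was higher (2.32, 2.20 to 2.45), with the regulatory list higher in 10 of 12 members (1.00). Within clusters that list was higher in cluster 4 (0.85), lower in clusters 1 (-1.10), 7 (-0.44) and 8 (-0.46), and within the central range of random lists in clusters 0 (-0.39) and 3 (-0.10). Frmd5 (5.39) and Wdr19 (4.48) were among the 5 highest genes.

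Naive and memory genes had a class median of 0.89, interferon gamma response genes 0.97, MHC class I genes 0.49, dissociation stress 0.67 and the unfolded protein response 0.48, all above the central range of random lists. Within clusters, naive and memory genes were higher in clusters 1 (1.23) and 7 (1.30), lower in clusters 3 (-0.91) and 4 (-0.82), and within that range in clusters 0 (0.014) and 8 (-0.18). Interferon gamma response genes lay within it in clusters 3 (0.10) and 8 (-0.26), MHC class I genes in clusters 1 (0.33) and 8 (-0.0044), and the unfolded protein response in cluster 1 (0.033). Glycolysis (-0.43) and proliferation (-0.90) were below it over the class, but glycolysis lay within it in clusters 4 (0.022) and 8 (-0.071). Proliferation was below it in none of the 6 clusters, being higher in clusters 0 (0.81), 3 (0.52) and 4 (0.46) and within it in clusters 1 (0.14), 7 (-0.15) and 8 (-0.10). Oxidative phosphorylation (-0.14) and the 4 measured non-immune genes (0.023) lay within it, except that oxidative phosphorylation was below it in cluster 1 (-0.29, percentile 0.63). Clusters 1 and 2 held most PBS cells (1411 and 1179, against 138 and 48 in EM), and clusters 0 and 3 most EM cells (1846 and 941, against 142 and 153 in PBS). In regulatory T-like cells the type I interferon median was 1.98, Pdcd1 was higher (1.31, 0.75 to 1.93), Ctla4 lower (-0.95, -1.03 to -0.87), and for Foxp3 the interval included equality (-0.09, -0.21 to 0.04), while in cluster 3, which held 153 PBS and 941 EM cells of this subset, Foxp3 was lower (-0.30, -0.44 to -0.17).

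NK cells had higher type I interferon genes in EM, in all 25 members (median 1.69, percentile 100). Ifng stood at 31.2 and 181 CPM (2.54, 2.04 to 3.08), Xcl1 at 209 and 2125 CPM (3.34, 3.16 to 3.54) and the chemokine Ccl1 at 1.74 and 224 CPM (7.01, 5.15 to 10.06). Prf1 (-0.77), the death ligand gene Fasl (-1.70), the chemokine Ccl5 (-1.10) and Serpinb9b (-2.98) were lower, and Gzmb stood at 4227 and 4019 CPM (-0.07), with its sign turned by size factors (0.067). Cytotoxicity genes were higher in 9 of 17 members (0.38, percentile 99.6) and inhibitory receptors lower in 11 of 14 (-0.54, percentile 0.58), with Rgs16 at 1.96 and Entpd1 at -1.82. The cytotoxicity median lay within the central range of random lists with equal weight per cell (0.15), without the UMI minimum (0.15) and with a pseudocount of 10 CPM (0.26), and the inhibitory median with that pseudocount (-0.33). Dissociation stress (0.92), the unfolded protein response (0.82), interferon gamma response (0.55), MHC class I (0.45) and proliferation (0.35) had medians above the central range of random lists. The proliferation median turned to -0.24 without the UMI minimum and lay within the range with equal weight per cell (0.30, percentile 97.2). Naive and memory (-0.24), glycolysis (-0.24) and oxidative phosphorylation genes (0.13) lay within it, but oxidative phosphorylation lay above it with equal weight per cell (0.24, percentile 98.8). Median-of-ratios scaling gave a size factor of -0.14 on the log2 scale, by which each NK ratio would be higher, and of -0.10 in regulatory T-like cells.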

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

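Of the tests in this part, the one on the UMI minimum for neutrophils was set before its result was seen, and the tests on free RNA, clusters, sex or library, cell calling, pooled sexes and the unnamed cluster were chosen after the result was seen.

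Some gene lists moved in opposite directions in different cell classes, which drew attention to them. Dissociation stress genes had a median log2 ratio of -2.28 in microglia (17 of 20 lower) and 0.67 in T cells (15 of 20 higher). Proliferation genes had a median of 2.04 in microglia (15 of 17 higher) and -0.90 in T cells (16 of 18 lower). Within the 6 T clusters with at least 100 cells of each library, dissociation stress medians lay between 0.55 and 0.81, while proliferation medians lay between -0.15 and 0.81 and none was below the central range of random lists, so the lower proliferation value holds for the T class as a whole. Cluster 7, with Top2a and Mki67 among its leading genes, was 12.3% of PBS T cells and 5.95% of EM T cells. The smaller cluster 26, with Mki67 and Stmn1 among its leading genes, was 0.609% and 1.61%. The differences between the classes were not tested.

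The type I interferon list was higher in EM in every class compared. Free RNA of EM macrophages is argued against: the median list member stood in EM T cells at 44.2% of its monocyte/macrophage level, against 0.475% for the median of 12 macrophage markers. Different clusters holding the classes are argued against as the whole account in T cells. There the medians lay between 0.99 and 2.45 in the clusters with at least 100 cells of each library. In monocyte/macrophage cells only cluster 9 (2.18) bears on it, with 175 of the 1611 PBS cells. These values were below the class medians (2.72 and 2.73), so the mix of clusters may still add to the difference. The NK class was cluster 5 alone, so it cannot test this explanation. In dendritic cells the lowest median over the 3 clusters, each with at least 20 cells of each library, was 1.51. That argues against different clusters as the whole account there. For microglia this explanation stays open, because no cluster had more than 15 cells of its rarer library. An effect of EM is a hypothesis, but the sex of the animals or another library difference cannot be told apart from it with 1 library in each group.

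No EM cell was named a neutrophil, against 644 in PBS. A fall in depth as large as that of T cells is argued against. PBS neutrophils thinned by the T cell ratio of median UMIs (0.4706) passed the cell filter in 88.0% of cases (567 of 644, 95% interval 85.3 to 90.5%). Class medians fell further in monocyte/macrophage cells (9176 to 1337 UMIs) and microglia (8096 to 900.5), and less in NK cells (2895 to 2170.5). In those 2 myeloid classes mostly different clusters were compared. Within monocyte/macrophage clusters 9 and 14 medians fell from 1589 to 865.5 and from 4062 to 3340. Within dendritic clusters 18, 23 and 25 they fell from 9933 to 3272.5, from 7795.5 to 2121 and from 7050 to 4916.5. A fall larger than that of T cells was not simulated, so the thinning cannot decide on it. Neutrophils captured in EM and dropped at cell calling would leave free RNA, but S100a8 and S100a9, markers of neutrophils, had 207 UMIs in PBS T cells and 0 in EM T cells, an upper limit of 2.90% of the PBS level. A loss of neutrophils during tissue handling or the sort, a sex difference and an effect of EM all stay open and may each account for it.

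An unnamed cluster of the PBS library, cluster 32, stood out as a signal outside the classes compared, with 47 cells and none in EM. Animals of both sexes pooled in each library are argued against, since a Y-linked UMI was found in 0.335% of EM T cells and Xist in 0.128% of PBS T cells at 1000 UMIs, against 30.9% and 28.5% in the other library. In cluster 32, however, 100% of the 47 cells had an Xist UMI (9 of them also a Y-linked UMI), Ptprc, the gene of CD45, stood at 2.30% of its T cell level, and 86.7% of the PBS Xist UMIs lay there. Its leading genes included Krt18 (900.4 CPM), Alb (857 CPM) and Lbp (826 CPM). These values are consistent with cells that are not leukocytes of the PBS animals, while their origin stays open, and the sex of the animals is confounded with treatment.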

How the results depend on the processing

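Chosen after seeing the data were 5 alternatives: cluster 16 counted with neutrophils, removal of the 6% highest doublet scores, clusters 0, 10 and 11 left out, cluster 9 alone and subtraction of T cell RNA. Of 591 recomputed list medians, 443 stayed within counting error, 139 moved, and 9 turned that had lain outside the central range of random lists. Among those that stayed or moved, 30 medians, all of lists within that range, also changed sign. A total of 30 medians outside the range lay within it or beyond its other side, and 25 within it lay outside. Of 2075 single-gene ratios 1623 stayed, 437 moved and 15 turned (1 more, with an interval including equality, changed sign), and of 71 shares and ratios of shares 59 stayed, 10 moved and 2 turned. The type I interferon median stayed above 0 under each alternative run in each class, between 2.18 and 2.90 in monocyte/macrophage cells (14 alternatives) and between 1.04 and 1.33 in microglia (5 alternatives). On list medians, the stricter cell filter, both resolutions, centring, both doublet settings and thinning were run in monocyte/macrophage cells only. Microglial list medians were thus not recomputed under the filter that turned the microglial share. The alternative activation median stayed between -2.18 and -0.90, and the regulatory T-like ratio of shares between 5.24 and 6.27. The cause of the differences below was not tested. Depth limits the EM myeloid values: 229 of 386 microglia and 259 of 689 monocyte/macrophage cells had under 1000 UMIs. No paired analysis was possible because each group has 1 library and no value comes from a test.

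Under the stricter cell filter the ratios of shares were 1.20 (T), 0.232 (monocyte/macrophage), 2.40 (NK), 0.620 (microglia) and 4.73 (dendritic). Monocyte/macrophage medians were then 0.059 (classical activation), -1.94 (alternative activation), -0.086 (immunosuppressive), 2.89 (type I interferon), 0.79 (interferon gamma) and -0.77 (MHC class II). Single genes turned to -1.03 (Apod) and -2.56 (Clec10a) in monocyte/macrophage cells, -0.29 (Ccl5) in microglia, and 0.95 (Mrc1) and 0.35 (Fcgr2b) in dendritic cells.

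At resolution 2.0 the ratios of shares were 0.503 (monocyte/macrophage) and 3.36 (dendritic), and monocyte/macrophage medians were 0.15 (classical activation), -2.18 (alternative activation), -0.15 (immunosuppressive), 2.87 (type I interferon) and 0.78 (interferon gamma). With centring within each library the classical activation median was 0.071.

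With equal weight per cell, monocyte/macrophage medians were -1.12 (classical activation), -1.25 (alternative activation), 0.15 (lipid-associated), 2.25 (type I interferon), -0.056 (interferon gamma), 0.15 (MHC class II) and 0.14 (lysosome). The dendritic chemokine median was -0.0097 and the T inhibitory median -0.98. Tgfb1 (-0.36), Hk1 (-0.11) and Pdia4 (0.31) turned in monocyte/macrophage cells and Hsp90b1 (0.016) in T cells.

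Thinning to 1000 UMIs left out 259 of 689 EM and 54 of 1611 PBS monocyte/macrophage cells, so their mix changed too. Thinned to 1000 UMIs, the monocyte/macrophage medians were -1.99 (alternative activation) and 0.32 (interferon gamma). Pdia4 (0.14) and Cenpf (0.41) turned there, Cxcl10 (-0.039) and Ndufs6 (-0.33) in dendritic cells and Hsp90b1 (0.064) in T cells. A pseudocount of 10 CPM gave type I interferon medians of 2.59 (monocyte/macrophage), 1.91 (dendritic), 2.04 (T) and 1.46 (NK), and T medians of 0.92 (regulatory) and -0.84 (inhibitory). Size factors gave T medians of 1.08 (regulatory), 0.50 (cytotoxicity), -0.83 (inhibitory) and 2.80 (type I interferon), and turned Gzmb in NK cells to 0.067. Without the UMI minimum the dendritic chemokine median was -0.083 and the NK proliferation median -0.24.

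Without clusters 0 and 11 (T) and cluster 10 (monocyte/macrophage), the ratios of shares were 0.750 (T) and 0.572 (monocyte/macrophage). The T medians were then 1.61 (regulatory), -0.58 (cytotoxicity) and -0.81 (inhibitory). Cluster 9 alone gave -1.10 (classical activation), -1.45 (alternative activation), 0.52 (lipid-associated), 2.18 (type I interferon), 0.53 (MHC class II) and 0.46 (lysosome). Without the highest doublet scores the type I interferon median was 2.90, and with T cell RNA subtracted the MHC class II median was -0.21.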

Other observations

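In the EM library the monocyte/macrophage genes Kdr, Bcl11a and Apod, which had some of the highest ratios of the class, lay mostly in cluster 14, at 108, 238 and 158 CPM. Plasmacytoid dendritic cells of the same library expressed Kdr at 394, Bcl11a at 826 and Apod at 122 CPM. Siglech, a plasmacytoid marker, stood at 33.4 CPM in cluster 14 and 3106 CPM in the plasmacytoid cells, and Ccr9 at 54.2 and 2817 CPM. Under the stricter cell filter and at resolution 2.0, 111 and 110 EM cells of cluster 14 lay in a cluster led by Cd209a, Bcl11a and Kdr that was classed as dendritic there. These genes were looked up after their values were seen.

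The EM cells of clusters 9 and 12, with medians of 865.5 and 884 UMIs, had less of the nuclear RNA Malat1 than EM T cells, at 508 and 635 CPM against 2857 CPM. Xist, also nuclear, stood at 72.6 and 117 CPM there and at 408 CPM in EM T cells. The T cell gene Cd3e stood at 169 and 142 CPM in these clusters and at 1101 CPM in EM T cells. The PBS cells of cluster 9 had Cd3e at 138 CPM, against 838 CPM in PBS T cells. In PBS, Malat1 stood at 1077 CPM in cluster 9, 2282 CPM in cluster 20, which held most PBS microglia, and 1979 CPM in T cells.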
